A study of Caenorhabditis elegans with 6 samples.

How the data were processed

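MicroRNAs (miRNAs) were measured in whole adult Caenorhabditis elegans of 2 temperature-sensitive germline mutants, fem-2(b245ts) and fem-3(q20ts), kept at 25 °C and collected on day 1 of adulthood, 24 hours past the late L4 larval stage. Short RNAs were purified on gels, ligated to a Cy3-carrying oligonucleotide and hybridised to 1-colour spotted arrays, per the labels. Each miRNA oligo was printed 4 times. Per the labels, each genotype had 2 biological replicates, the first on 2 technical arrays and the second on 1 array, so that 6 arrays stood for 4 biological samples. The arrays of both genotypes that carry the same biological replicate number also share a date-like token in their descriptions. The labels do not say what it marks, and it was read here as an array batch, named A for replicate 1 and B for replicate 2.

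The deposited value table holds linear spot intensity scaled by the authors on the total intensity of each array, and all 6 columns had the same sum. Scanner files of the 4 arrays of replicate 1 were also used. In these files the deposited normalized intensity equalled the mean spot intensity minus the median background intensity to within 0.005, and the value table equalled it times 1 factor per array, with a tolerance of 0.1%, on all spots but 2: 1 spot of miR-256 on a fem-3(q20ts) array and 1 spot of a contaminated oligo on a fem-2(b245ts) array. The signal-to-noise score of each spot, as given per the file headers, exceeded 3 for 49.0% to 69.3% of the spots of an array. Per the file headers, the percent of saturated pixels was above 0 for 4 spots of 1 fem-3(q20ts) array and for 0 spots of the other arrays. The scanner, its software and the probe sequences are not given in the sources used here. Spot names were taken from the scanner files and joined to the value table by spot number. For the arrays of batch B, which were used without a scanner file, the layout was checked by the spread of the spots sharing a name: its median SD was 0.20 and 0.18 on the log2 scale, against 2.19 and 2.49 with shuffled names. This check shows that spots sharing a name held the same oligo. It cannot show that the oligo was the named one.

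Intensities were floored at the 10th percentile of the positive values (12.8), log2-transformed and averaged over the spots of an oligo, and technical arrays were averaged into 1 biological sample. An oligo was tested if its mean over the 4 biological samples exceeded the detection level, the 95th percentile of the 32 Buffer spots averaged over the samples (an intensity of 36.5). This kept 94 of 108 miRNA oligos. Of the 108 names, 100 matched a miRNA gene of the WBcel235 annotation, which was used for chromosomes and neighbours only.

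Differences were coded as fem-3(q20ts) minus fem-2(b245ts) and tested two-sided with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact permutation test of 2 samples against 2 cannot give a two-sided p below 0.333, so significance rests on limma's variance shared across oligos (2 residual and 3.05 prior degrees of freedom). Fold differences are 2 raised to the difference of mean log2 values. An oligo not above the 95th percentile of the Buffer spots on any array of a genotype has only a bound there. The bound sets the brighter genotype's mean against, per array, the lowest miRNA signal above the Buffer level. Fixed lists of miRNAs (14 seed families, clusters and functional lists, and the miRNAs encoded on chromosome X) were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 15 lists. The lists were the miR-35, let-7, lin-4, miR-51, miR-58, miR-2, miR-44, miR-72, miR-75 and miR-238 families, the miR-64 cluster, somatic tissue markers, ageing-associated miRNAs, heterochronic miRNAs and X-linked miRNAs.

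The named miRNAs followed a rule. In each direction they were the 10 with the largest difference of 1 sign in both replicates, those past the threshold first. Added to these were every member of the miR-35 family and, for each other list, the member with the largest and, in lists of 3 or more, the one with the smallest absolute difference. The lists, the rule, the test and most alternatives were fixed before the data were examined. For the within-batch values and the replicate block, the replicate numbers were taken to pair the samples, on the reading of the shared token as a batch. The main fit was unpaired, so variation that both genotypes share within a replicate stayed in its standard errors. Across the tested oligos, the difference of replicate 1 minus replicate 2 correlated between the genotypes (r = 0.711, oligos not being independent). The alternatives chosen beforehand were a replicate block, quantile normalization, median centring, another scaling to the total, other filters and floors, single technical arrays, all 6 arrays with duplicateCorrelation, a trended robust eBayes, each biological sample left out, camera with an estimated correlation, fry, and the scanner files of replicate 1 (normexp with an offset of 50, then quantile normalization). Scaling on miRNAs, on miRNAs outside the miR-35 family or on the spike control, subtraction of the median Buffer spot and removal of oligos that differed by over 3 on the log2 scale between the batches were added after seeing the data.

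The procedure was tested on simulated data: 50 simulated data sets were drawn for the comparison of the genotypes from the measured means and spreads, each with 30 of the 94 miRNAs changed. It called 13.2% of the changes of 1, 66% of the changes of 2 and 87.2% of the changes of 4 on the log2 scale, and 5.13% of its calls were of unchanged miRNAs. The simulated samples varied independently, without the variation that the genotypes share within a replicate. Array noise was taken from the technical arrays of fem-3(q20ts) alone. Array and spot noise were added to a spread between samples that already holds both. The simulated data were noisier than the measured data in this respect, so the shares of changes called may be too low. The rates hold for that setting only. The number of arrays limits the precision.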

Results

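The arrays compared adult animals of 2 genotypes that differ in the gametes they make. At the restrictive temperature the germ line of fem-2(b245ts), a loss-of-function mutant of the sex determination pathway, makes oocytes and no sperm, whereas that of fem-3(q20ts), a gain-of-function mutant, makes sperm and no oocytes. Each genotype was represented by 2 biological replicates on 3 arrays. The arrays were scaled to the same total intensity, and their median spot intensity ranged from 101 to 178. Between 63 and 104 of the 108 miRNA oligos were above the Buffer level of a given array. Of these oligos, 94 passed the filter on mean signal and were tested.

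The comparison asked which miRNAs differed between adults with an oogenic and adults with a spermatogenic germ line. The signal of miR-35 to miR-41 was far lower in fem-3(q20ts) than in fem-2(b245ts). These 7 miRNAs belong to the miR-35 family, which is known to be abundant in oocytes and embryos and to be needed for embryonic development. Together they made up 11.8%, 14.2% and 13.9% of the miRNA signal on the 3 fem-2(b245ts) arrays and 0.353%, 0.390% and 0.478% on the 3 fem-3(q20ts) arrays. A single miRNA, miR-243, passed the test in the other direction. In all, 8 of 94 miRNAs passed the threshold in limma, 7 lower and 1 higher in fem-3(q20ts). At an unadjusted p under 0.05 there were 8 lower and 2 higher.

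Within the miR-35 family, miR-36 had an intensity of 2299 ± 41.3 in fem-2(b245ts) and 102 ± 19.9 in fem-3(q20ts) (SD, n = 2 biological samples each). Its log2 difference was -4.50 (SE 0.32; limma adjusted p = 0.000905), a 22.7-fold difference. miR-35 was 1734 ± 601 in fem-2(b245ts) and 112 ± 7.16 in fem-3(q20ts) (SD, n = 2), which was 14.9-fold lower and the smallest difference of the 7 (log2 difference -3.90, SE 0.37; limma adjusted p = 0.00194). miR-39 was 1842 ± 39.5 in fem-2(b245ts) and 58.4 ± 8.22 in fem-3(q20ts) (SD, n = 2), which was 32.6-fold lower (limma adjusted p = 0.000761). The log2 differences of miR-37, miR-38 and miR-40 were -6.22, -5.02 and -5.77, with limma adjusted p-values of 0.000905, 0.000905 and 0.00409. In fem-3(q20ts), miR-38 was above the Buffer spots on 2 of 3 arrays, and miR-37 and miR-40 on 1 of 3. miR-41 was above them on 0 of 3, so that it was at least 23.2-fold lower in fem-3(q20ts). The limma test of miR-41 (adjusted p = 0.000585) was of its log2 difference of -5.59 and not of this bound. Its fem-3(q20ts) intensities of 12.2 to 13.7 lay at about the floor of 12.8. Flooring narrows their spread (SD 0.0086 on the log2 scale) and so can lower this p. For miR-35, miR-36 and miR-39, which were above the Buffer spots on all arrays, the differences were -3.60, -4.68 and -5.24 within batch A and -4.19, -4.32 and -4.81 within batch B.

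The genes of miR-35 to miR-41 are consecutive miRNA genes on chromosome II. The gene of the remaining family member, miR-42, lies apart from them on the same chromosome, next to those of miR-43 and miR-44. The intensity of miR-42 was 117 ± 7.82 in fem-2(b245ts) and 53.4 ± 16.7 in fem-3(q20ts) (SD, n = 2), and it was above the Buffer spots on 2 of 3 arrays of each genotype. Its log2 difference of -1.25 (SE 0.40) did not pass over all miRNAs (limma adjusted p = 0.261). All 8 members passed when adjusted over the list alone, against 7 over all miRNAs tested. For miR-42 the limma p adjusted over the list was 0.025, the same as unadjusted, because the adjustment leaves the largest p of a list unchanged. That call of miR-42 was lost in 7 of 21 fits: after quantile normalization (-0.75), median centring (-0.89), scaling on the spike control (-0.69) or Buffer subtraction (-1.50), and without fem-2(b245ts) replicate 1 (-1.33) or 2 (-1.18) or fem-3(q20ts) replicate 1 (-0.82). As a list, the miR-35 family lay below the other miRNAs by its median (list minus rest, -5.21), with a camera adjusted p of 4.36e-17. With an estimated correlation the list did not pass (camera adjusted p = 0.451). Fry, which tests the members against no change and not against the other miRNAs, gave an adjusted p of 0.0564 and passed in 7 of 21 fits. miR-43 and miR-44 had log2 differences of -0.87 and -0.08 and did not pass.

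**Figure D1:**
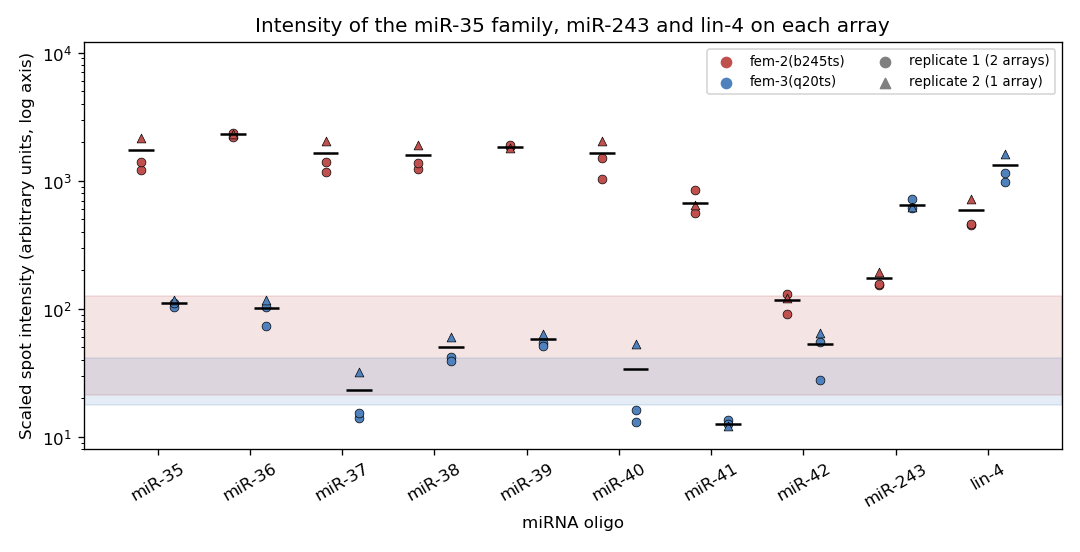
Intensity of the 8 miRNAs of the miR-35 family, miR-243 and lin-4 on each array (vertical log axis, arbitrary units), with circles for replicate 1, triangles for replicate 2 and black lines for the mean of the 2 biological samples. Shaded bands span the 95th percentiles of the Buffer spots on the arrays of each genotype, and miR-35 to miR-41 lie above both bands on every fem-2(b245ts) array and between 12.2 and 117 on the fem-3(q20ts) arrays.

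miR-243, a miRNA known to be loaded into the Argonaute RDE-1, had an intensity of 175 ± 28.4 in fem-2(b245ts) and 647 ± 27.8 in fem-3(q20ts) (SD, n = 2). Its log2 difference was 1.89 (SE 0.31; limma adjusted p = 0.0187), with 2.10 within batch A and 1.68 within batch B. The call was lost when any 1 biological sample was left out, with limma adjusted p-values of 0.061 to 0.181 and differences of 1.72 to 2.06. lin-4, the heterochronic miRNA that represses lin-14, had the next largest positive difference, 1.18 (SE 0.40), with 1.22 within batch A and 1.15 within batch B. It did not pass in the unpaired main fit (limma adjusted p = 0.299), but passed with the replicate as a block (limma adjusted p = 0.0417).

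The other miRNAs named for a large mean difference that was positive in both replicates did not pass the test. Their log2 differences were 0.87 for miR-79, 0.83 for miR-247, 0.79 for miR-77, 0.75 for miR-60, 0.73 for miR-232, 0.73 for miR-80, 0.72 for miR-46 and 0.66 for miR-86, with limma adjusted p-values from 0.379 to 0.625. Some were uneven between the replicates: miR-247 was at 1.33 in replicate 1 and 0.32 in replicate 2, and miR-232 at 0.22 and 1.24. miR-247 was above the Buffer level on 1 of 3 fem-2(b245ts) arrays. On the other side, miR-61 had a log2 difference of -1.03 (limma adjusted p = 0.379). Of the 86 miRNAs that were not called, 83 had a difference within 1 on the log2 scale. The median standard error was 0.37. Of all 94 miRNAs, 73 differed in the same direction in both replicates.

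**Figure D2:**
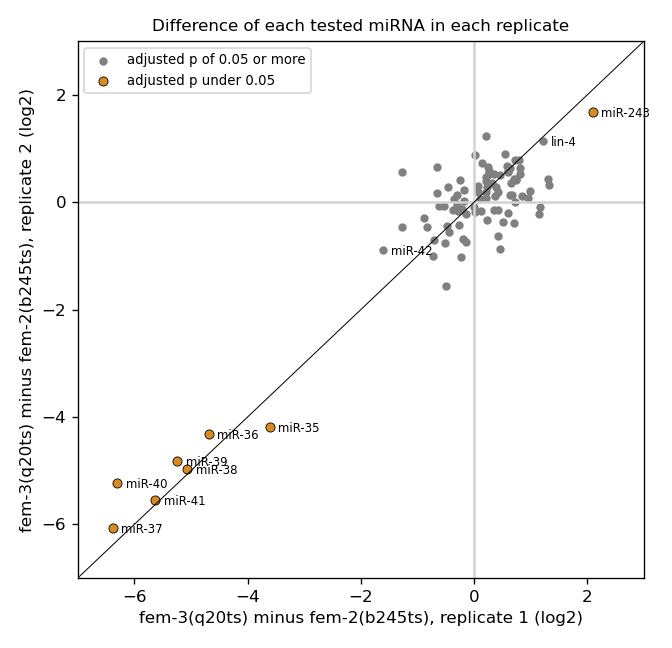
Difference of each of the 94 tested miRNAs between fem-3(q20ts) and fem-2(b245ts) in replicate 1 (horizontal axis, log2) and replicate 2 (vertical axis, log2), with the line of equal values. The 7 called miRNAs at the lower left are miR-35 to miR-41, and miR-243 lies at the upper right.

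None of the other 14 lists passed in camera (adjusted p of 0.460 or more) or in fry (0.257 or more). In fry, 3 of them passed under some other settings. In the main fit, 0 members of these lists passed the limma threshold, also when adjusted over the list alone. Under other settings some passed over the list alone. Among them were 2 of 2 in the lin-4 family after quantile normalization and 1 of 2 after median centring. In the miR-75 family 1 of 2 passed under each of these settings. All 4 members of the miR-58 family, relatives of bantam in flies, had positive differences, from 0.20 for miR-58, which turned negative under another scaling, to 0.73 for miR-80. The miR-72 family lay below the rest by its median (list minus rest, -0.59), with differences of -0.35 for miR-72 and -0.50 for miR-74. On the spike control both differences were positive, and so was that of miR-72 under median centring, but these scalings shift all miRNAs together and left the list at -0.59 relative to the rest. It was at -0.96 without fem-2(b245ts) replicate 2 and at -0.40 without fem-2(b245ts) replicate 1. The lin-4 family (0.70), the miR-75 family (0.47), the miR-64 cluster (0.41) and the miR-51 family (0.36) had medians above the rest, with miR-229 at 0.63 and miR-56 at 0.60. The miR-64 cluster was at 0.11 after quantile normalization and at 0.20 without fem-2(b245ts) replicate 1. Without that sample the miR-75 family was at 0.29 and the miR-51 family at 0.058, and without fem-3(q20ts) replicate 2 the lin-4 family was at 0.43 and the miR-51 family at -0.030. In the let-7 family, which acts in developmental timing, 3 of 4 tested members had positive differences, from miR-241 at 0.07 to miR-48 at 0.34, a count that was 1 of 4 after scaling on the miRNAs outside the miR-35 family, and the list differed from the rest by -0.03 (-0.25 without fem-2(b245ts) replicate 1 and 0.020 without fem-2(b245ts) replicate 2). The heterochronic list, which shares these members and adds lin-4 and miR-237, differed by 0.12, by -0.014 after quantile normalization and by 0.023 without fem-2(b245ts) replicate 1. Medians relative to the rest were 0.20 for the miR-2 family, with miR-250 at 0.33, -0.25 for the miR-44 family and -0.22 for the miR-238 family, in which miR-238 was at -0.08 and miR-239b at -0.26. Leaving out 1 biological sample gave -0.12 (fem-2(b245ts) replicate 2) to 0.28 for the miR-2 family, -0.61 (fem-3(q20ts) replicate 2) to -0.14 (fem-3(q20ts) replicate 1) for the miR-44 family, and -0.45 (fem-3(q20ts) replicate 2) to -0.27 for the miR-238 family.

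Markers of tissues outside the germ line gave no list difference past the threshold. Of the 7 tested somatic markers, 5 had positive and 2 negative differences, against 4 and 3 on the miRNAs outside the miR-35 family and 7 and 0 on the spike control, with a median 0.31 above the rest (camera adjusted p = 0.460). Without fem-3(q20ts) replicate 1 that median was 0.078. Among them were miR-60, known from the intestine (0.75), and miR-71 (-0.05). The ageing-associated miRNAs differed from the rest by -0.12, with miR-246 at 0.54, and by -0.25 without fem-3(q20ts) replicate 1 and -0.051 without fem-2(b245ts) replicate 1. Of the 23 tested miRNAs in the X-linked list, 17 had positive and 6 negative differences, from -0.86 for miR-271 to 0.83 for miR-247, miR-49 being the smallest at 0.08. The counts were 10 and 13 on the miRNAs outside the miR-35 family, 21 and 2 on the spike control, and 11 and 12 without fem-2(b245ts) replicate 1. The X-linked list lay 0.23 above the rest (camera adjusted p = 0.460), at -0.053 without that sample and at -0.0066 without fem-3(q20ts) replicate 2. Of the 94 tested names, 86 matched the annotation. Names without a match were counted with the rest whatever their chromosome, and so was miR-56* (0.18), which matched chromosome X. Other scalings moved the median difference of all tested miRNAs from 0.14 to between -0.19 and 0.70, and all but quantile normalization shift the miRNAs of an array together. Of the 94 differences, 24 changed sign on the spike control, 20 under median centring, 19 after quantile normalization, 17 on the miRNAs outside the miR-35 family and 6 on all miRNAs, and 0 of these miRNAs had been called. Among the miRNAs named here they were those of miR-44, miR-49, miR-51, miR-58, miR-66, miR-71, miR-72, miR-74, miR-238, miR-239b and miR-241.

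By SD, the spread between arrays of one RNA sample was smaller than that between biological replicates. By the median absolute difference the 2 were close in fem-2(b245ts), at 0.41 between technical arrays and 0.48 between biological replicates. In fem-3(q20ts) these medians were 0.24 and 0.42. Over the tested miRNAs, the SD of the log2 differences between technical arrays was 0.51 in fem-2(b245ts) and 0.31 in fem-3(q20ts). Between biological replicates, which also differ in array batch, it was 0.79 and 0.75.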

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

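The tests of array background, of scaling and of cross-hybridisation in this part were chosen after the results were seen.

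Signal outside the miRNA oligos drew attention because it exceeded the Buffer spots. Among the oligos that the files name tncR, 9 exceeded the detection level and all 9 had a lower mean in fem-3(q20ts), but only tncR2 and tncR23 were above the Buffer level on all arrays. Of the others, tncR4 and tncR7-1 were above it on 1 of 3 arrays of each genotype, and tncR29 on 2 of 3. The largest difference was that of tncR13, at -3.19 on the log2 scale (limma adjusted p = 0.00598 among 103 oligos), with intensities of 132 ± 16.8 in fem-2(b245ts) and 11.6 ± 5.41 in fem-3(q20ts) (SD, n = 2). It was above the Buffer level on 2 of 3 fem-2(b245ts) arrays and on 0 of 3 fem-3(q20ts) arrays, so that it was at least 4.63-fold lower. As a group, the tncR oligos had a camera p of 0.0281, and 0.147 with an estimated correlation.

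Whether the lower tncR signal lies in the RNA or in the arrays stayed open for the group. Their median difference minus that of the miRNAs outside the miR-35 family was -0.92 (-1.06 in replicate 1 and -0.46 in replicate 2), a contrast within each array that scaling to one total cannot make. For tncR2 and tncR23 alone it was -0.94 in replicate 1 and -0.74 in replicate 2. After subtraction of the median Buffer spot, 8 of the 9 were tested, with a median of -0.80 against -0.76 for the same 8 before. tncR13 was at -3.72 and still passed (limma adjusted p = 0.0142), a size that is not exact because its fem-3(q20ts) signal was not above the Buffer level. Its fem-2(b245ts) intensity was 120 in replicate 1 and 144 in replicate 2. The median Buffer spots there were 25.9 and 12.2 (replicate 1) and 5.51 (replicate 2), which argues against the median background as its whole cause. The 95th percentile of the Buffer spots was itself lower in fem-3(q20ts), mostly in replicate 1 (-1.63, against -0.26 in replicate 2), where tncR13 lay near that level in fem-2(b245ts), and all 10 unnamed oligos had lower means (medians of -0.39 and -0.94 in replicates 1 and 2). For the tncR oligos, a background that differs between the arrays therefore cannot be told apart from a difference between the genotypes. For tncR13 this holds for background above the median, which subtraction of a median does not remove. The next largest difference, that of tncR5, was -1.80 in replicate 1 and -1.74 in replicate 2, and it passed only with the replicate as a block.

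Of the 10 unnamed oligos, 3 exceeded the detection level. The signal of 4 oligos differed by over 3 on the log2 scale between the array batches in both genotypes: tncR29 and tncR10 were brighter in batch A, and the unnamed oligo emc141 and miR-264 in batch B. These oligos were chosen after their values were seen. Names on the batch B arrays were taken over from the batch A layout, so a change of layout at these spots was not excluded.

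For the lower miR-35 to miR-41 signal in fem-3(q20ts), scaling and background were weighed first. The median difference of the 7 was at most -4.47 over the scalings of the value table. From the scanner files of replicate 1 with normexp and quantile normalization it was -3.98. These values argue against scaling as the whole cause. The Buffer spots differed by a mean of -0.37 after flooring at 12.8. Their medians were 3.56 to 25.9, so the floor limits how far that mean could fall. Their 95th percentile differed by -0.95. On the fem-2(b245ts) arrays the 7 had intensities of 558 or more, against 95th percentiles of 21.4 to 127. After Buffer subtraction the 7 were at a median of -5.35. The last 2 results argue against background as the whole cause. Cross-hybridisation among these related sequences could not be decided: the 3 members above the Buffer level on all arrays differed from one another in their log2 differences by up to 1.13 (SE 0.39, or 2.86 standard errors, miR-35 against miR-39) and by up to 13.8 standard errors (0.52, SE 0.038, miR-36 against miR-39), which speaks against equal falls, but their signal in fem-3(q20ts) lay only 1.23 to 6.55 times above that level. A biological difference that the design names, the presence or absence of oocytes, stays open as a hypothesis that these arrays do not separate from other effects of the 2 mutations. For the 8 miRNAs past the threshold, the 3 ways to split 4 samples into pairs are too few to give a share under 0.05: 1 of 3 splits, the real one, gave 8, and the highest of the others gave 2.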

How the results depend on the processing

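The scalings on miRNAs or the spike control, the Buffer subtraction and the removal of batch-dependent oligos were chosen after seeing the data. The 7 lower miRNAs, miR-35 to miR-41, were called in each of the 21 limma fits, the 4 without a biological sample included, and the total count stayed between 7 and 9. The count of higher miRNAs was 1 except with the replicate block, where it was 2 with lin-4 added, and without any 1 biological sample, where it was 0 (range 0 to 0) and miR-243 was lost with fewer samples in the fit; a lone sample was then assumed to vary like the other genotype. Among the oligos named tncR, the block added tncR5 (-1.77, adjusted p = 0.0112, against 0.212 without it). It changed no other call of a miRNA, of a tncR oligo or of a list in camera. The shift of the miR-35 family from the other miRNAs (-5.21) did not pass with an estimated correlation (adjusted p = 0.451), and fry, a test against no change, gave 0.0564; over the refits the shift ranged from -5.55 to -4.95. Its camera call held in all 21 fits at the preset correlation and in none with an estimated one (adjusted p of 0.074 or more). In fry the family passed in 7 of 21 fits: quantile normalization (0.00323), median centring (0.0333), the 25th percentile floor (0.0451), technical array 2 (0.0387), all arrays (0.000412), all miRNAs (0.0329) and miRNAs outside the family (0.0252). Fry also called the somatic markers under median centring (0.0333) and all arrays (0.0122), the miR-64 cluster on all miRNAs (0.0329) and the miR-238 family on all miRNAs (0.0485) and on those outside the family (0.0252); in camera these lists passed in 0 of 21 fits. The ratio of biological to technical spread stayed within 1.5 times of 1.56 in fem-2(b245ts) and 2.40 in fem-3(q20ts). It was lowest with the detection level doubled, at 1.21 and 1.96. Scaling again to the total could move nothing, because all columns already had the same sum, and this fit repeats the main one among the 21. The scanner files of replicate 1, which allow no test, gave smaller differences for miR-35 to miR-41, from -4.31 to -2.96, with a median of -3.98. Signal over background limits the folds of miR-37, miR-38, miR-40 and miR-41. Outside the miR-35 family, 54 of 86 miRNAs were higher, and 37 after scaling on those miRNAs, 48 on all miRNAs, 73 after quantile normalization, 74 after median centring and 78 on the spike control. Of all tested miRNAs, 24 changed sign on the spike control, 20 under median centring, 19 under quantile normalization and between 9 and 19 without 1 sample, 0 of them called; only the named miRNAs and the lists are given next. Median centring and the scalings on miRNAs or the spike control shift all miRNAs together; for the other settings the cause was not tested. Under quantile normalization they were miR-238 (0.24), miR-239b (0.28), miR-44 (0.13), miR-66 (0.094) and the heterochronic list (-0.014). Under median centring they were miR-238 (0.28), miR-239b (0.11), miR-44 (0.29), miR-51 (0.012), miR-66 (0.18), miR-71 (0.31) and miR-72 (0.018). On the spike control they were miR-238 (0.48), miR-239b (0.30), miR-44 (0.48), miR-51 (0.21), miR-66 (0.38), miR-71 (0.51), miR-72 (0.22) and miR-74 (0.063). On miRNAs outside the family they were miR-241 (-0.26), miR-49 (-0.25) and miR-58 (-0.13), and on all miRNAs miR-241 (-0.052) and miR-49 (-0.045). With technical array 2 they were miR-238 (0.019), miR-44 (0.10) and miR-71 (0.086), and with technical array 1 the let-7 family (0.0072). Without the filter they were the let-7 family (0.10) and the ageing-associated list (0.0095), and with all 6 arrays the let-7 family (0.014). Leaving out 1 sample gave -0.47 to 0.30 for miR-238, -0.53 to 0.37 for miR-44, -0.98 to 0.28 for miR-51, -0.19 to 0.085 for miR-71, -0.20 to 0.34 for miR-241, -0.057 to 0.46 for miR-58, -0.24 to 0.39 for miR-49, -0.25 to 0.020 for the let-7 family, -0.053 to 0.25 for the X-linked list, -0.12 to 0.28 for the miR-2 family and -0.030 to 0.58 for the miR-51 family. Of the values of the named miRNAs under all alternatives, 762 kept direction and side of the threshold or moved within the replicate spread. Of the others, 39 changed sign in a refit, 44 moved beyond that spread, 4 lost the threshold and 1 gained it. For the within-batch and scanner values, which are not refits, a change of sign was counted only for called miRNAs. Not counted were miR-44, miR-49, miR-58, miR-238, miR-241 and miR-246, whose signs differed between the batches (miR-246 at 1.17 in A and -0.085 in B). In the scanner files miR-238 (0.26) and miR-49 (-0.014) also had the other sign.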

Other observations

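The test in this part was chosen after the result was seen. Outside the miR-35 family, 54 miRNAs had positive and 32 negative differences, with a median of 0.19 on the log2 scale. A candidate explanation is the scaling of each array to one total that holds the miR-35 family, since a family that takes a large share of the signal in one genotype lowers all other values there. That total also holds oligos other than miRNAs. The miRNAs made up 78.7%, 76.8% and 94.1% of it on the fem-2(b245ts) arrays and 89.8%, 90.0% and 96.3% on the fem-3(q20ts) arrays. With scaling on all miRNAs, the family included, the median outside the family was 0.068. When the arrays were scaled on the miRNAs outside the family, their median became -0.14. That scaling centres the same miRNAs whatever the cause, so it does not decide between the explanation and a real rise, and on the spike control the median was 0.75. The spike control itself differed by -0.56, at -0.50 in replicate 1 and -0.62 in replicate 2.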
